A study of Rattus norvegicus with 2 samples.

How the data were processed

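Gene expression was measured by poly(A)-selected RNA sequencing in RBL-2H3 cells, a rat basophilic leukemia line that is widely used as a mast cell and basophil model. The 2 libraries were 1 of untreated cells and 1 of cells incubated with IgE, both wild type. The labels give no dose, no duration and no statement on whether an antigen was added. The groups were taken from the treatment label of each sample.

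The authors deposited a table of raw read counts per gene name with their own log2 fold change, p-value and adjusted p-value for the comparison of the 2 libraries, per the file headers, and a second table that is a subset of it. The submitters' processing notes name fastp 0.23.0, HISAT2 2.1.0, DESeq2 1.18.1 and the rat build rn6, without saying which step each served. The counting tool, its strand setting and its treatment of reads that map to several places are not given in the sources used here. The files give no gene coordinates, so none are printed.

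The table of all genes held 16990 rows but 14913 distinct names. The other 2077 rows repeated, with identical values, a name already listed (157 names, mostly small RNA families such as U6, which stood in 796 identical rows), and each name was kept once. The adjusted p-values in the authors' deposited table also correspond to 14913 tests. Of the names, 2043 were Ensembl identifiers, of which 0 could be paired with a symbol in the RefSeq gene table at hand, while 11267 names matched a symbol there (assembly GRCr8). Some genes of the lists below were not analysed here. Reads from near-identical copies and overlapping genes cannot be separated from these counts.

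The deposited log2 fold changes, p-values and adjusted p-values were recomputed to within 4.67e-08, 3.47e-08 and 3.32e-08 by edgeR's exact test on the 14913 genes with plain library totals and a fixed dispersion of 0.01, which is a coefficient of variation of 0.1 between replicates. With 1 library per condition that value is an assumption, and the p-values in the authors' deposited table rest on it rather than on replicates. The subset table held the 451 names with an absolute log2 fold change of 1 or more and an unadjusted p under 0.05 in the authors' deposited table.

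From the counts, log2 CPM (read counts scaled to a common library size) were computed with edgeR 4.0.16 (R 4.3.3), with TMM scaling and a prior of 0.5 counts. Genes with 20 or more reads over both libraries were kept, which left 12102. A positive log2 fold means higher in the IgE library. Each group is 1 library, so no test across samples was made. Differences were described by a fixed rule of size, a 2-fold difference, and single genes carry an exact Clopper-Pearson 95% interval of the read ratio. These intervals cover counting error only, since reads are not shown to be independent molecules and no replicate culture was sequenced. The total count was 20917968 reads in the untreated library and 26268330 in the IgE library, so that the count of 3 reads taken as the detection floor corresponds to 0.143 and 0.115 CPM.

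Before the data were examined, 23 gene lists were fixed, of which 16 were pathways. The other lists were cytosolic ribosomal proteins, mitochondrial genome transcripts, housekeeping genes and markers of macrophages, neutrophils, lymphocytes, and fibroblasts and epithelia. For each list with at least 5 measured members, the median log2 fold was placed among the medians of 10000 random lists of the same size matched on expression in 10 bins. The percentile describes these 2 libraries and is not a p-value. Named genes were fixed by rule as the 12 highest and 12 lowest log2 folds among genes with a symbol, the 2 highest and 2 lowest members of each pathway list, the 3 receptor subunits, and the 5 most abundant genes of the untreated library. Names that are only an identifier (Ensembl, clone, LOC, RGD, Gm or Rik names) were passed over, of which the clone, Gm and Rik names were added to that rule after the values were seen. Some genes that this rule names are not reported here. Other genes named were chosen after their values were seen and are marked as such.

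The calculation was tested on simulated data for this comparison, with 200 of 14913 genes changed. Of the 100 genes changed by a log2 of 1.5, 99% were recovered as at least 2-fold apart, and of the 100 changed by a log2 of 3, 97%. Of 11894 unchanged genes, 63 passed the same rule. The simulated counts carried counting error only, so these figures do not cover variation between cultures. Alternatives were library totals or DESeq2 1.42.0 size factors in place of TMM, a prior of 5 counts, no minimum or a minimum of 100 reads, a 1.5-fold rule, and list medians without the most extreme member. No gene lacked an adjusted p in the authors' deposited table, so leaving out such genes removed none. Percentiles of lists without their most extreme member were added after the list medians were seen.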

Results

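The data comprised RNA-seq read counts from 1 untreated and 1 IgE-treated library of RBL-2H3 rat basophilic leukemia cells, with 20917968 and 26268330 counted reads. The series set out to look at events downstream of IgE acting through its high-affinity receptor. At least 1 read was counted for 14024 genes in the untreated and 14078 in the IgE library. The 10 most abundant genes took 5.0% and 5.1% of the reads. There were no replicate libraries, so every difference given here is between 2 libraries and has no replicate check. Among the 5 most abundant untreated transcripts, Mt-co1 stood at 14637 and 15925 CPM (read counts scaled to a common library size) in the untreated and IgE library, Actb at 6961 and 6710, Eef2 at 5466 and 5165, Mt-cyb at 3626 and 4038, and Hsp90ab1 at 3443 and 3269.

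Both libraries carried the transcripts of the tetrameric IgE receptor. Ms4a2, the beta chain, was at 1252 CPM in untreated and 1375 CPM in IgE-treated cells. Fcer1a, the IgE-binding alpha chain, was at 534.9 and 675.6 CPM, and Fcer1g, the gamma chain, at 37.9 and 44.1 CPM. Their log2 folds were 0.13 (95% counting interval 0.11 to 0.16), 0.34 (0.30 to 0.37) and 0.22 (0.09 to 0.35). Of 25 measured genes of the receptor and its proximal signalling, none differed by 2-fold between the libraries. Fcer1a and Fcer1g were the 2 highest, and the phospholipase Plcg2 (-0.26) and the phosphoinositide kinase subunit Pik3cd (-0.24) the lowest. The list median was -0.01, at percentile 36.7 of matched random lists.

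The question of the comparison was which genes differ between IgE-treated and untreated cells. The transcriptomes lay close together. The genes with a symbol, 500 or more reads and at least a 2-fold difference were Ccl2, Egr1 and Nfkbiz, all higher with IgE, and further immediate early genes and Nfkbid were at least 2-fold higher on fewer reads. Ccl2, which encodes a monocyte chemoattractant, went from 6.15 to 29.5 CPM, a 4.78-fold difference (log2 2.26, counting interval 1.99 to 2.54). Egr1, a zinc-finger transcription factor, went from 13.1 to 30.4 CPM (log2 1.22, 1.02 to 1.42). Nfkbiz and Nfkbid, both nuclear members of the IkappaB family, had log2 folds of 1.07 (0.83 to 1.32) and 1.28 (0.78 to 1.82).

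Of 12102 genes over the minimum, 161 were at least 2-fold higher and 157 at least 2-fold lower with IgE, and 11784 lay between. Among the 5079 genes with 2000 or more reads the SD of the log2 fold was 0.14. The genes at least 2-fold apart were mostly weakly expressed. They had a median of 34 reads (higher) and 33 reads (lower) over both libraries, against 1402.5 for all tested genes. With 100 or more reads, 21 genes were at least 2-fold higher and 15 lower. With 500 or more reads there were 4 higher genes, Ccl2, Egr1, Nfkbiz and LOC100362453, and 0 lower ones. Draws from the same libraries with no difference but counting error gave on average 66.8 genes at least 2-fold apart, against the 318 observed.

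**Figure D1:**
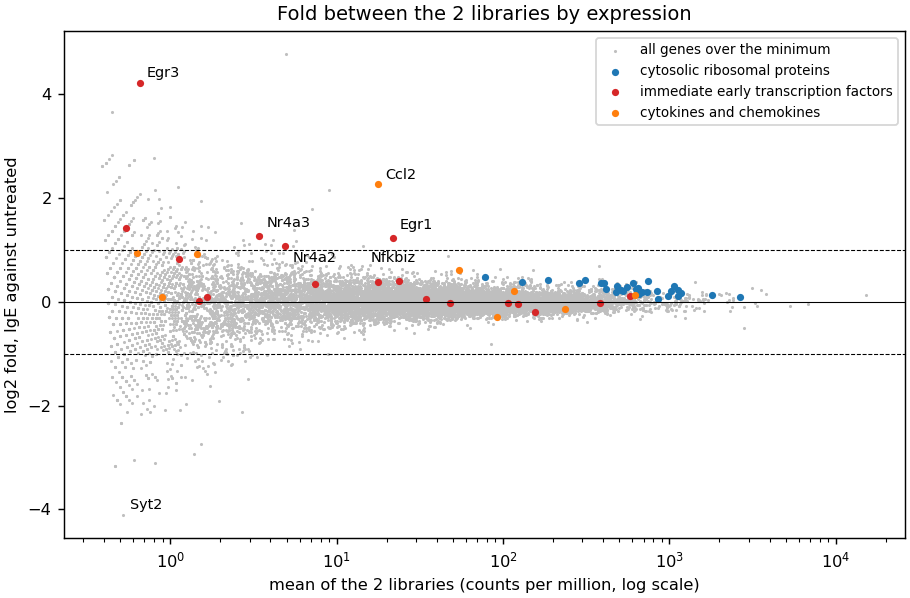
Log2 fold of IgE against untreated cells (vertical) by mean expression in CPM (horizontal, log scale), with each gene over the minimum as a point, 3 gene lists in colour and dashed lines at 2-fold. Genes at least 2-fold apart lie mostly at low expression, with Ccl2, at a log2 fold of 2.26, and Egr1, at 1.22, among the exceptions, and the 30 ribosomal protein genes of the list lie above 0.

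Of the pathway lists, immediate early transcription factors had the highest median. Of 18 measured members, 5 were at least 2-fold higher, 0 at least 2-fold lower, and 13 lay between. The 5 were Egr3, Nr4a1, Nr4a3, Egr1 and Nr4a2, the Nr4a genes being orphan nuclear receptors. Egr3 had 1 read in the untreated and 33 in the IgE library (log2 4.22, counting interval 2.15 to 10.1), and the value was 2.50 with a prior of 5 counts. Nr4a1 had 6 and 21 reads (1.42, 0.13 to 3.09), Nr4a3 42 and 127 (1.27, 0.76 to 1.82), and Nr4a2 66 and 174 (1.07, 0.66 to 1.51). Fos had a log2 fold of 0.40 (0.23 to 0.58). The lowest members were Jund (-0.20) and Myc (-0.05), and Jun was at -0.03. The list median of 0.22 stood at percentile 99.95 of matched random lists, and without Egr3 it was 0.12, at percentile 96.6. Cytosolic ribosomal protein transcripts, with a median of 0.23, and mitochondrial genome transcripts, with 0.16, were shifted in the same direction by about as much as this median.

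Feedback inhibitors of MAP kinase signalling had the third highest median of the pathway lists. None of 11 measured members reached 2-fold, 8 were above 0 and 3 below. Spry1, an inhibitor of receptor tyrosine kinase signalling, went from 2.76 to 5.35 CPM (log2 0.95, 0.50 to 1.42). Dusp6, an ERK phosphatase, went from 57.2 to 82.3 CPM (0.53, 0.42 to 0.63). Dusp7 (-0.35) and Spred2 (-0.28) were lowest. The median was 0.19, at percentile 99.4, and 0.18 without Spry1, also at percentile 99.4. Both medians were again no larger than that of the ribosomal protein transcripts.

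**Figure D2:**
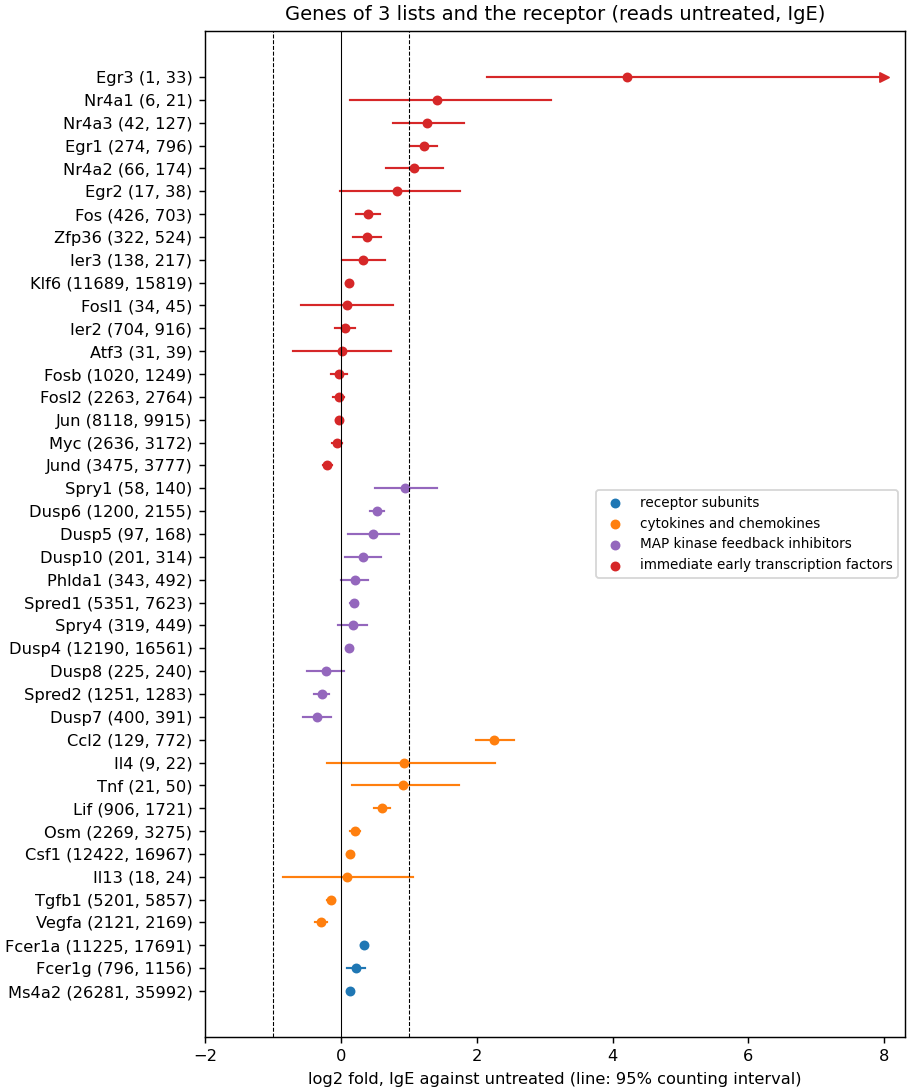
Log2 fold of IgE against untreated cells (points) with the 95% counting interval (lines) for the measured genes of the immediate early, MAP kinase feedback and cytokine lists and for the receptor subunits, with reads in the untreated and IgE library in brackets. The interval of Egr3 runs on past the axis to 10.1, and Ccl2 has the highest fold of the cytokine list, 2.26.

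Of 27 genes in the cytokine and chemokine list, 9 were measured, of which 1, Ccl2, was at least 2-fold higher and 8 lay between. Those not analysed here included Il5, Il6, Il10, Csf2, Ccl3 and Ccl4, and those under the minimum of reads included Il3, Il9 and Ccl7. Tnf (21 and 50 reads, log2 0.92, counting interval 0.17 to 1.74) and Il4 (9 and 22 reads, 0.94, -0.21 to 2.27) were close to 2-fold but rested on few reads. Lif, which encodes leukemia inhibitory factor, went from 43.2 to 65.7 CPM (0.61, 0.49 to 0.72). Vegfa (-0.29) and Tgfb1 (-0.15) were the lowest, and Il13 (18 and 24 reads) was at 0.09. The median of the 9 measured genes was 0.21, at percentile 99.4, and 0.17 without Ccl2, at percentile 97.8. The ribosomal protein median of 0.23 and the mitochondrial median of 0.16 lay in the same direction by about as much.

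Among 17 measured NF-kappaB targets and regulators, Nfkbid and Nfkbiz were at least 2-fold higher and the other 15 lay between. Rela (-0.23), the p65 subunit, and Nfkb2 (-0.19) were lowest. The list median of -0.01 was at percentile 34.9, and the mean was 0.16, of the opposite sign. With a minimum of 100 reads the median was 0.02.

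The measured transcripts for stored mediators were close to level. Of 26 genes in the granule protease and mediator list, 14 were measured, and none of these reached 2-fold. Those not analysed here included Mcpt2, Mcpt8, Tpsab1 and Tpsb2. Hdc, which makes histamine, stood at 374.0 and 376.6 CPM (log2 0.01, -0.03 to 0.05). The mast cell carboxypeptidase Cpa3 was at 0.27, the chymase-family genes Mcpt9 and Cma1 at 0.34 and 0.28, Mcpt1 at -0.22, and Tph1, which makes serotonin, at -0.11. The median was 0.02, at percentile 69.0. Of 11 eicosanoid synthesis genes none reached 2-fold, and the median was 0.01, at percentile 60.1, or -0.03 with a minimum of 100 reads. Alox15 (0.64, 24 and 47 reads) and Mgst2 (0.34, 34 and 54 reads) were highest and Ptges2 (-0.15) and Lta4h (-0.06) lowest, while Ptgs2, the inducible cyclooxygenase, was at 0.26.

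Of 22 exocytosis genes, 1 was at least 2-fold lower, the synaptotagmin gene Syt2, with 21 reads untreated and 1 with IgE (log2 -4.10, counting interval -10.1 to -2.08). The others lay between, from Rab3a (-0.17) to Scamp1 (0.24) and Vamp8 (0.26), with a list median of -0.01 at percentile 37.6 that was 0.00 without Syt2. The calcium and NFAT list (17 measured) ranged from Nfatc1 (-0.24) and Nfatc2 (-0.18) to Calm2 (0.25) and Trpm4 (0.39), with a median of 0.02 at percentile 68.5. The BCL2 family (10 measured) ranged from Bcl2l2 (-0.21) and Bbc3 (-0.04) to Bax (0.24) and the pro-apoptotic Bcl2l11 (0.40), with a median of 0.00 at percentile 50.1 whose sign differed between scalings (-0.01 with library totals).

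Metabolic, stress, interferon and proliferation lists held no gene at least 2-fold apart among members over the minimum of 20 reads. Of 5 interferon members under it, Irf9, named after its values were seen, had 1 and 13 reads (log2 2.91, counting interval 0.65 to 8.79) and was in the authors' deposited list. Cholesterol synthesis (21 measured) had a median of -0.01 at percentile 44.8 and a mean of 0.01, with Idi1 (0.28) and Tm7sf2 (0.22) highest and Srebf2 (-0.16) among the lowest. Glycolysis (19) had a median of 0.00 at percentile 48.7, with Slc16a3 (0.48, 16 and 28 reads) and Ldha (0.14) highest and Pfkl (-0.19) and Pfkfb3 (-0.19) lowest. The unfolded protein and amino acid stress list (17) had a median of 0.06 at percentile 90.8, with Dnajb9 (0.26) and Sdf2l1 (0.25) highest and Sesn2 (-0.26) and Phgdh (-0.09) lowest. Heat shock chaperones (10) had a median of 0.04 at percentile 78.8, with Hspe1 (0.34) and Hspd1 (0.22) highest and Bag3 (-0.16) and Hsp90ab1 (-0.08) lowest. The interferon list (11) had a median of -0.04 at percentile 24.1 and a mean of 0.05, with Ifi27 (0.36) and Psmb9 (0.24) highest and Oasl (-0.12) and Irf1 (-0.11) lowest. The cell cycle list (28) had a median of -0.03 at percentile 20.1, with Cdkn1a (0.15) and Cdk1 (0.12) highest and Ccnd1 (-0.30) and Aurka (-0.15) lowest.

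**Figure D3:**
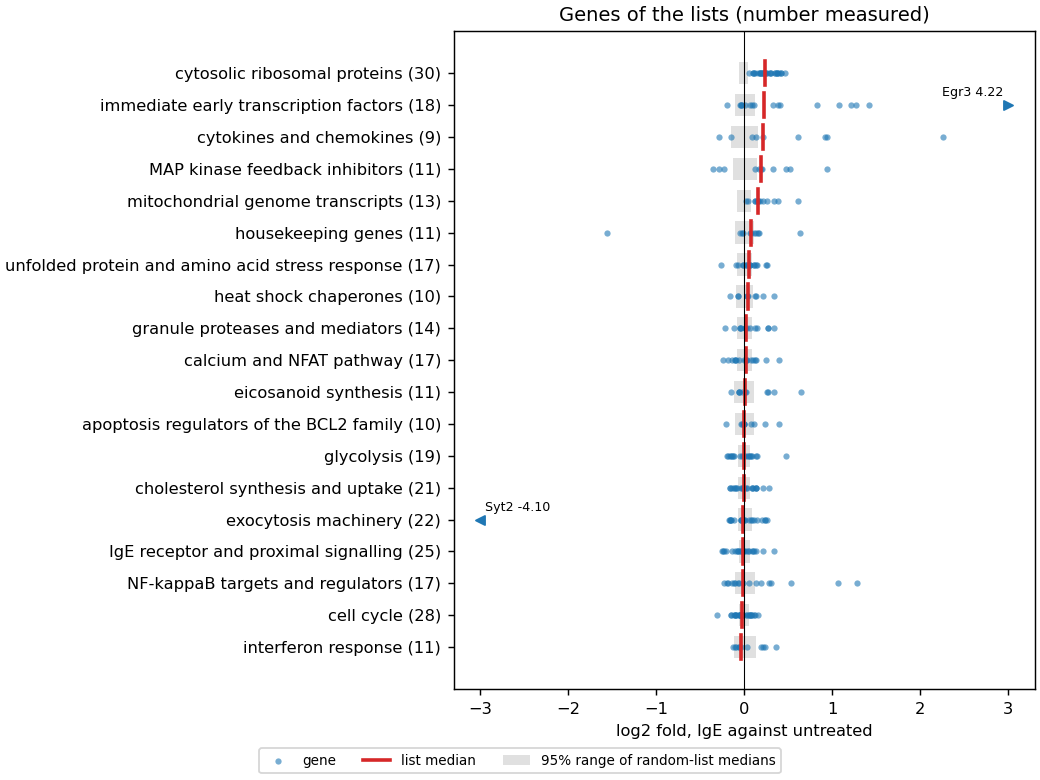
Log2 fold of IgE against untreated cells (horizontal) for each measured gene (points) of the 19 lists with at least 5 members, with the list median in red and the 95% range of medians of matched random lists in grey. The medians of 5 lists lie beyond that range, namely ribosomal proteins at 0.23, immediate early factors at 0.22, cytokines at 0.21, MAP kinase feedback inhibitors at 0.19 and mitochondrial transcripts at 0.16. Without Egr3 the immediate early median was 0.117, inside its random range, which ended at 0.125.

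All 30 measured cytosolic ribosomal protein genes were above 0, from Rps2 (0.06) to Rps12 (0.47), with a median of 0.23 at percentile 100 of the random lists. All 13 protein-coding mitochondrial genome transcripts were above 0, from Mt-atp8 (0.03) to Mt-nd3 (0.61), with a median of 0.16 at percentile 99.99. They took 3.41% of the untreated and 3.79% of the IgE reads. The 11 housekeeping genes had a median of 0.08 at percentile 92.3 and a mean of -0.03. Eef1a1 lay at -1.56 but was counted at 34 and 14 reads, few for an elongation factor whose mRNA is abundant in most cells. Ribosomal protein genes and Eef1a1 have near-identical copies in the genome, so their counts are uncertain.

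Most markers of other cell types were not analysed here. Of 14 macrophage markers, 3 were measured, Cd68 (43 and 40 reads), Csf1r (46 and 37) and the scavenger receptor gene Msr1 (26 and 7). Of 12 neutrophil markers, 1, Ngp, passed the minimum (26 and 39 reads). Of 14 lymphocyte markers, Cd79a (214 and 296 reads) and Lck (108 and 124) were among those counted. Of 13 fibroblast and epithelial markers, Col3a1 stood at 281.3 and 252.8 CPM and Thy1 at 144.6 and 147.6 CPM.

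The 12 highest log2 folds among genes with a symbol were, besides Egr3 and Ccl2, those of Gbp1 (2.75), an interferon-inducible GTPase, the oxidised LDL receptor Olr1 (2.73), Gemin7l1 (2.63), the orphan receptor Gpr82 (2.60), the splicing regulator Mbnl2 (2.39), Gpx8 (2.39), the mitochondrial carrier Slc25a53 (2.20), Dynlt2 (2.14), the deiodinase Dio2 (2.02) and Nectin4 (1.98). These 10 had at most 8 reads in the untreated library. The counting intervals were 0.96 to 6.14 for Gbp1, 1.21 to 5.26 for Olr1, 1.09 to 5.16 for Gemin7l1, 0.79 to 6.0 for Gpr82, 0.82 to 4.94 for both Mbnl2 and Gpx8, and 1.17 to 3.56 for Slc25a53. With a prior of 5 counts Gbp1 was at 1.67, Olr1 at 1.85, Gemin7l1 at 1.76, Gpr82 at 1.55, and Mbnl2 and Gpx8 at 1.57. Among the 12 lowest were Syt2 and Kel (-3.17), a blood group antigen, the kisspeptin receptor Kiss1r (-3.17), the organic anion transporter Slco4c1 (-3.04), Kcp (-2.34), Phf11b (-2.34), Msr1 (-2.13), Pced1b (-2.09), the centrin Cetn1 (-1.97), Klhl32 (-1.96) and Clvs1 (-1.82). These had 18 to 42 reads untreated and 1 to 13 with IgE. The counting interval was -6.64 to -1.43 for both Kel and Kiss1r and -5.64 to -1.53 for Slco4c1. With a prior of 5 counts Syt2 was at -2.28, Kel and Kiss1r at -1.89, Slco4c1 at -2.0, and Kcp and Phf11b at -1.55.

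In the authors' deposited table of selected genes, 211 names were listed as up and 240 as down with IgE. The selection rested on an unadjusted p, and 199 of the 451 names had fewer than 20 reads over both libraries. In the authors' deposited table, 39 of the 451 had an adjusted p under 0.05, of which 22 were up and 17 down. Those with a symbol and a place in a list above were Ccl2 (5.67e-16), Egr1 (0.000232), Egr3 (0.00159), Nfkbiz (0.00857), Syt2 (0.00857), Nfkbid (0.0302) and Nr4a3 (0.0381), given as the adjusted p in the authors' deposited table. These values were recomputed with a coefficient of variation between replicates fixed at 0.1. A coefficient of 0.1 shared by all genes would give the genes with 2000 or more reads a log2 fold SD of 0.204, against 0.140 in these libraries, and no replicate gives its size in weakly expressed genes.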

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

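The count of genes at least 2-fold apart depended on how weakly expressed genes were handled. Against 161 higher and 157 lower, a prior of 5 counts gave 104 and 99, no minimum gave 855 and 875, a minimum of 100 reads gave 21 and 15, and a 1.5-fold rule gave 443 and 427. Library totals in place of TMM gave 161 and 161, DESeq2 size factors 161 and 157. In 2 alternatives chosen after seeing the data, keeping the repeated rows gave 165 and 162, and asking that the counting interval exclude no change gave 138 and 138. The median of all genes moved by at most 0.01 on the log2 scale under these scalings (-0.0092 with library totals). The prior and the minimum act on genes with few reads by construction. At an adjusted p under 0.01 the authors' deposited list held 16 names in place of 451. A 2-fold rule in the same table tests nothing, since the list was selected on that fold. Of 114 alternative list medians, 113 stayed within the list's counting interval. The exception was the mitochondrial list, at 0.153 with library totals, which lower every fold alike. The sign of the median differed for 4 lists near 0, namely eicosanoid synthesis, exocytosis, NF-kappaB and the BCL2 family. The immediate early median was 0.117 without Egr3 or with a minimum of 100 reads. Of 270 alternative folds of named genes, 269 stayed within the gene's counting interval (the exception was Mt-co1 with library totals), and none changed sign where that interval excluded 0. No paired analysis was possible because each group is 1 library, and no library could be left out for the same reason. Most genes at least 2-fold apart had under 100 reads, so counting error is large for them. Whether depth or variation between cultures limits these genes more was not tested.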

Other observations

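Several genes outside the named sets stood apart. Smad7, an inhibitor of TGF-beta signalling, went from 256 to 587 reads (log2 0.88, counting interval 0.66 to 1.10), and Crem, a cAMP-responsive transcription factor, from 252 to 516 (0.71, 0.49 to 0.94). Rasgrp3, an activator of Ras, had 39 and 106 reads (1.11, 0.58 to 1.69). Socs3, a feedback inhibitor of cytokine signalling, was lower, at 164 and 109 reads (-0.91, -1.27 to -0.55). Vom2r3, a vomeronasal receptor gene, had 67 and 288 reads (1.78, 1.40 to 2.19). Of the unnamed features, ENSRNOG00000067388 had 7 and 252 reads (4.76, 3.79 to 6.18), the highest log2 fold over the minimum, and LOC100362453 had 317 and 1136 (1.52, 1.34 to 1.71). ENSRNOG00000067077 (92 and 26 reads, -2.12) and ENSRNOG00000067565 (56 and 10 reads, -2.74) were lower. The abundant feature AY172581.24, named only by a sequence identifier that the files do not pair with a gene, had 69229 and 60565 reads (-0.51, -0.53 to -0.50). All genes of this paragraph were chosen after their values were seen.

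A further pair, chosen in the same way, also differed. Rps27a, a ubiquitin and ribosomal protein fusion, had 6037 and 12138 reads (0.69), and its pseudogene Rps27a-ps1 had 2260 and 1603 (-0.81). Counts of such near-identical copies are uncertain, and the reads of both together gave 0.41.

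All tests that follow were chosen after the results behind them were seen. Several families of small proteins were higher with IgE beyond the cytosolic ribosomal proteins. A scan of 25 name patterns was made first, and 5 families of small proteins were taken from it by judgement, with no fixed limit. Cytosolic ribosomal proteins by name (71 genes, 70 above 0) had a median log2 fold of 0.29, and the Nduf genes of respiratory complex I (43 genes) had one of 0.21, Cox genes (16) 0.23, Atp5 genes (16) 0.33 and mitochondrial ribosomal proteins (73) 0.14. These medians had been seen when the families were taken, and Uqcr genes (7) at 0.18 and Psm genes (36) at 0.14 were not taken. Histone names (25), also of small proteins, had a median of -0.03 and were not taken. Other scanned names lay as far from 0 without belonging to such families, namely SNORD genes (7) at 0.31, Vom genes (10) at 0.28 and Snor genes (15) at -0.36. A further 51 genes for small proteins (Snrp and Lsm, Tomm, dynein light chains, Sec61 and Ost subunits) had a median of 0.19, and 64 genes for large proteins (Dock, Chd and Kmt, Abc, integrin alpha and plexin, myosin heavy chains) a median of -0.12. Of these further families, the dynein light chains (0.19), the Dock genes (-0.08) and the integrins and plexins (-0.08) lay within the 95% range of matched random lists. The medians of these further families had not been seen when the comparison was chosen, but values of single members had, and protein size was taken from general knowledge.

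A change of cytosolic translation genes alone is argued against by the further small-protein families without the members seen before, with a median of 0.180 over 48 genes, where the 95% range of matched random lists ended at 0.056. Whether the 13 mitochondrial genome transcripts share 1 change cannot be told apart from unequal changes. The SD of their log2 folds was 3.03 times that of counting error with an assumed coefficient of variation of 0.02, barely past the bound of 3 set for this test, and 0.759 times with a coefficient of 0.1, so the outcome rests on the assumption. The difference of 0.305 between the further small-protein and large-protein families (0.299 without the 7 members seen before) is consistent with a hypothesis that the libraries differ by a tilt toward short transcripts, as RNA integrity, fragment size or a real program of gene expression could give. Histone names, with a median of -0.03 in the scan, were not higher with IgE. Transcript lengths and GC content were not used here, so which of these sources applies stays open.

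Of 7 immediate early genes with 100 to 2000 reads, 3 (Egr1, Nr4a2 and Nr4a3) were at least 2-fold higher, or 42.9% (exact 95% interval 9.90 to 81.6%). That interval takes the genes as independent, which was not tested. The members with more reads (Fosb, Fosl2, Jun, Jund, Myc and Klf6) were not 2-fold higher. Counting error alone gave 0 such members in 1000 draws. Of 100 small-protein family genes with as many reads, 0 passed 2-fold (up to 3.62%). These values argue against counting noise and the tilt for Egr1, Nr4a2 and Nr4a3. Of 5 members with 20 to 99 reads, 2 (Egr3 and Nr4a1) were at least 2-fold higher, and counting noise is argued against for Egr3, at 4.22 where the 5 members reached at most 2.39 in the draws, but cannot be told apart for Nr4a1, since the draws also gave 1 of the other 4 members. Of 12 small-protein family genes with as few reads, 4 (33.3%) passed 2-fold, the highest of them at 2.14, below Egr3. That share cannot tell the tilt apart from a response for this pair, because the transcript lengths of Egr3 and Nr4a1 were not used here. The tilt also stays open for the list's median of 0.22. The small-protein families seen first have a median of 0.224, but similar medians cannot decide this, because transcript lengths were not used here. With 1 library per group, a difference between the 2 cultures other than IgE, such as handling or cell density, may also give higher Egr and Nr4a genes.

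The number of genes at least 2-fold apart may reflect more than IgE. Counting noise alone gave at most 87 genes in 100 draws, against 318 observed, so it does not account for all of them. Draws with a coefficient of variation of 0.1 between cultures, the value with which the deposited p-values were recomputed, gave on average 96.3, and 0.2 gave 389.6. A coefficient shared by all genes is argued against at both values by the SD of 0.140 (upper 95% bound 0.143) over the genes with 2000 or more reads, where 0.1 would give at least 0.204 and 0.2 at least 0.408. Variation between cultures that is larger in weakly expressed genes cannot be told apart from an effect of IgE by this number, because no replicate culture gives its size there.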
